A study of Clostridium autoethanogenum with 6 samples.

How the data were processed

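RNA was analysed from wild-type Clostridium autoethanogenum DSM 10061 grown in 10 ml of Tanner modified medium at 37 °C, an initial pH of 5.8 and 1.7 atm. There were 3 samples from the dark and 3 from white visible light of 4200 lux, all taken at 48 h. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq RNA kit. Groups and replicate numbers were taken from the sample titles. The labels do not say that the samples of a group were separate cultures, so p-values measure the spread between these samples, which can be technical.

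The authors deposited 1 table. Per the file headers it holds TPM for each sample, the mean TPM of each group as the authors computed it, a fold change (ratio of light to dark), its log2 value, a p-value and an adjusted p-value. The submitters' processing notes name Bowtie2, RSEM and DESeq2 without versions or roles, and the genome build is not given in the sources used here. The log2 fold changes in the authors' deposited table are not the log2 ratio of their TPM columns. They lay above it by a median of 0.86 for genes over 1000 nt and 1.34 for genes of up to 200 nt. All per-sample columns were used. Lengths came from the RefSeq table of assembly ASM148472v1, where 3889 of the 3964 loci matched by locus tag, and its coordinates were used for the neighbour of CLAU_2841 alone.

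The planned test was one for counts. As the table holds TPM, the test fixed beforehand for that case was used: limma (version 3.58.1 in R 4.3.3), without trend or robust moderation, on log2(TPM + 1), group only, for rows with a mean TPM of at least 1 in one group. Changes on this scale understate those of low genes. P-values were adjusted by the Benjamini-Hochberg method, with 0.05 as threshold. A second count required a 2-fold change. The model assumes residual spread shared across genes, and an exact test of 1 gene with 3 against 3 samples cannot go below p = 0.1. Of 25 gene lists fixed by patterns on the product text, 24 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. All tests were two-sided. The lists cover the pathways, complexes and cell states described in the results. Product text patterns also matched 29 members counted here as accidental, and lists were run again without them. These were picked out by product text after values had been seen.

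Named genes followed a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls among called genes with a mean TPM of at least 10, groups that do not overlap and an informative product. It added up to 4 called members of each list by smallest p, the 2 most abundant members of a list without a call, and a fixed set of central enzymes.

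On simulated TPM with 200 changed genes, made from the dark means and the spread within groups for light against dark (3279 genes tested), limma recovered 33.3% of 2-fold and 85.9% of 4-fold changes, with 5 calls among 3081 unchanged genes. Camera called the 1 changed list and 0 of 24 unchanged lists. The simulated spread was independent between genes, while the estimated correlations within the real lists were 0.13 to 0.65. The simulation therefore could not show false list calls that come from genes moving together. It also gave all other genes the same mean in both groups. The larger share of TPM that a few rows held in the real light samples, described in the results, was not built in. The 5 calls thus do not measure false calls that come from such a shift.

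TPM keeps no depth. Low TPM multiplied by length minus an offset came out within 0.1 of whole multiples of a step for 88.6% to 90.7% of the values used, against 27.2% to 32.5% with lengths shuffled. The offset estimates the mean fragment length and the step gives fragments on loci of known length, a lower bound of depth. A first search returned a step too small by a factor of 2 in 2 light samples, where at most 4.08% of multiples were odd, and a rule added after it doubled such steps. These estimates (Python 3.11.15, numpy 2.4.6, pandas 2.3.3) entered no test. Among rows above 0 in at least 1 sample, there were 15, 7 of them small RNA rows, in which all 6 values were identical to those of another row, for a cause that was not tested.

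Alternatives planned before the data were examined were pseudocounts of 0.1 and 10, no filter, the replicate number as a block, each sample left out, and the other list tests. Added after seeing the data were rescaling by the median of ratios or the upper quartile, leaving out the 3 most abundant rows or all small RNA rows, a filter at a mean of 10 TPM, trend and robust moderation, and lists without accidental members, together with the replicate block or fry after rescaling by the median of ratios. Figures were drawn with matplotlib 3.10.9.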

Results

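The data are RNA-seq profiles of Clostridium autoethanogenum DSM 10061, an anaerobic acetogen that grows on carbon monoxide, hydrogen and carbon dioxide and forms acetate and ethanol. Wild-type cells were grown on a gas phase of H2, CO and CO2 in the proportions 35, 50 and 15, and RNA was taken after 48 h. The design asks how white visible light of 4200 lux changes the transcriptome of cells that ferment gas, against growth in the dark. There were 3 dark samples and 3 light samples. Values were TPM, a transcript abundance scaled by gene length and library total, for 3964 annotated loci and for further small RNA rows without a name. Of all of these, 3530 had a mean TPM of at least 1 in one group and were tested with limma on log2(TPM + 1). TPM has the same total in every sample and does not hold the sequencing depth. An estimate from the steps between low values gave 5934544 to 6103615 fragments on loci of known length in the dark samples and 3295564 to 3998337 in the light samples.

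Light-grown samples differed from dark-grown samples over most of the transcriptome. All 4 genes of an arginine deiminase cluster and 4 genes of histidine breakdown rose by 20-fold or more in mean TPM, and a small heat-shock protein (CLAU_2044), an Hsp90-type chaperone (CLAU_0054) and a pair of xenobiotic exporters (CLAU_3930 and CLAU_3931) fell by more than 30-fold. After the median-of-ratios rescaling described below those rises were at least 40-fold, and the falls were 17.2-fold, 19.6-fold, 45.5-fold and 26.3-fold in the same order. Between samples of 1 group the Pearson correlation of log2(TPM + 1) across genes was 0.969 to 0.985 in the dark and 0.970 to 0.973 in the light, and between groups it was 0.807 to 0.836. Dark sample 2 stood apart on the second principal component of rescaled values (22.1, against -11.4 and -8.62 for the other dark samples), which held 5.88% of the variance. At a Benjamini-Hochberg adjusted p under 0.05 in limma, 2274 rows were called, 398 higher and 1876 lower in light. Of these, 1800 changed by at least 2-fold, 241 upward and 1559 downward. The groups did not overlap in 69.5% of tested rows in TPM without rescaling. Random order of the samples gives 10%, but that is no fair reference here. The scaling of the TPM columns also differed between the groups, as described below, and can by itself separate the values of an unchanged row. The share without overlap was not computed after rescaling.

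The excess of lower calls depended on scaling. A small RNA row, sRNA0049, held 30.02% ± 6.37 (SD, n = 3) of all TPM in the dark and 35.01% ± 2.21 (n = 3) in the light. CLAU_2841, annotated as a zinc ribbon domain protein, went from 3.21% ± 0.794 to 15.7% ± 0.444, and sRNA0041 from 2.89% ± 0.817 to 13.8% ± 0.991. Together these 3 rows took 36.1% ± 7.46 of TPM in the dark and 64.6% ± 2.06 in the light. The median tested row had a log2 change of -0.82 in TPM. With TPM rescaled by the median of ratios, an alternative added after seeing the data, the median log2 change was -0.0075 and 2103 rows were called, 1073 higher and 1030 lower. Both scalings called 1418 rows in common, all with the same sign; upper-quartile rescaling shared 1193 calls with TPM, 1124 of them with the same sign. In what follows, TPM values and TPM log2 changes come first, and "after rescaling" gives the change relative to the median gene. In the authors' deposited table, 2174 rows had an adjusted p under 0.05, 1108 of them higher in light and 1066 lower.

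**Figure D1:**
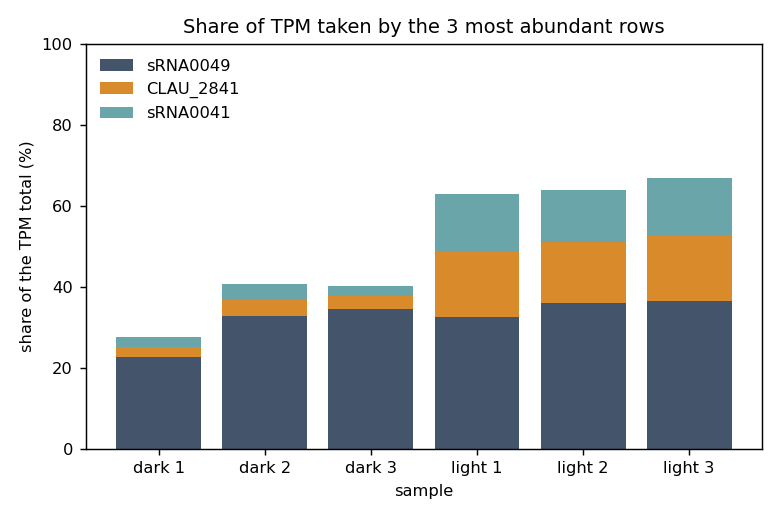
Stacked bars give the percentage of the TPM total in each of the 6 samples that falls on sRNA0049, CLAU_2841 and sRNA0041. The 3 rows together hold between 27.5% and 40.6% in the dark samples and between 63.0% and 66.9% in the light samples.

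All 4 neighbouring genes of the arginine deiminase pathway, which turns arginine into ornithine with formation of ATP, were among the largest rises. Arginine deiminase (CLAU_2940) went from 5.69 ± 2.37 TPM (SD, n = 3) in the dark to 606 ± 164 (n = 3) in the light, a log2 change of 6.54 ± 0.32 (SE; limma adjusted p = 1.8e-07). Ornithine carbamoyltransferase (CLAU_2941) went from 10.5 ± 4.53 to 717 ± 189 TPM, and carbamate kinase (CLAU_2943) from 6.97 ± 2.54 to 170.04 ± 45.6. The amino acid permease between them (CLAU_2942) rose by 4.17 on the log2 scale. Of the genes for histidine breakdown to glutamate, 4 were also among the largest rises. Urocanate hydratase (CLAU_0226) went from 1.40 ± 0.407 to 198 ± 36.3 TPM, with a log2 change of 6.37 ± 0.26 (limma adjusted p = 7.1e-08). Imidazolonepropionase (CLAU_0225) rose by 5.99, histidine ammonia-lyase (CLAU_0224) by 5.16 and glutamate formiminotransferase (CLAU_0228) by 4.05. Methylaspartate ammonia-lyase (CLAU_1856) and the E subunit of methylaspartate mutase (CLAU_1857), enzymes of glutamate fermentation, rose by 3.35 and 2.96. Translation elongation factor G (CLAU_1931) went from 58.5 ± 16.1 to 1109 ± 64.7 TPM. A putative membrane protein (CLAU_1466) was listed at 0 in all dark samples and at 20.05 ± 9.59 TPM in the light. These are the 12 largest rises under the naming rule, which passed over 18 rows without an informative product, 15 of them small RNA rows.

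The 12 largest falls under the naming rule include transporters, regulators and chaperones. Neighbouring genes for xenobiotic-transporting ATPases (CLAU_3930 and CLAU_3931) went from 578 ± 284 to 6.21 ± 0.534 TPM and from 634 ± 299 to 11.9 ± 1.13 TPM. The first had a log2 change of -6.19 ± 0.37 (limma adjusted p = 4.6e-07). A MarR family regulator (CLAU_3628) had a log2 change of -5.84, and the penicillinase repressor homologues CLAU_2692 and CLAU_1676 had -5.42 and -5.30. A ferredoxin-domain protein (CLAU_2332), a benzoate transport protein (CLAU_2328) and a molybdopterin-binding protein (CLAU_2331) lie close together and had -5.80, -5.69 and -5.44. The Hsp90-type chaperone htpG (CLAU_0054) went from 1165 ± 577 to 29.0 ± 5.03 TPM, and the small heat-shock protein Hsp20 (CLAU_2044) from 19411 ± 6273 to 559.8 ± 32.9. A sodium:dicarboxylate symporter (CLAU_2435) had -5.28 and a ubiquitin-associated-domain protein (CLAU_3751) had -5.13. The rule passed over 10 rows here, 7 of them small RNA rows. Dark sample 2 was the lowest dark sample in all 12 of these falls, for example at 566 TPM for CLAU_0054 against 1716 and 1212. Without it the 12 falls kept their calls, with log2 changes from -6.64 to -5.34. Each of the 24 largest changes kept its direction and its call after rescaling.

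**Figure D2:**
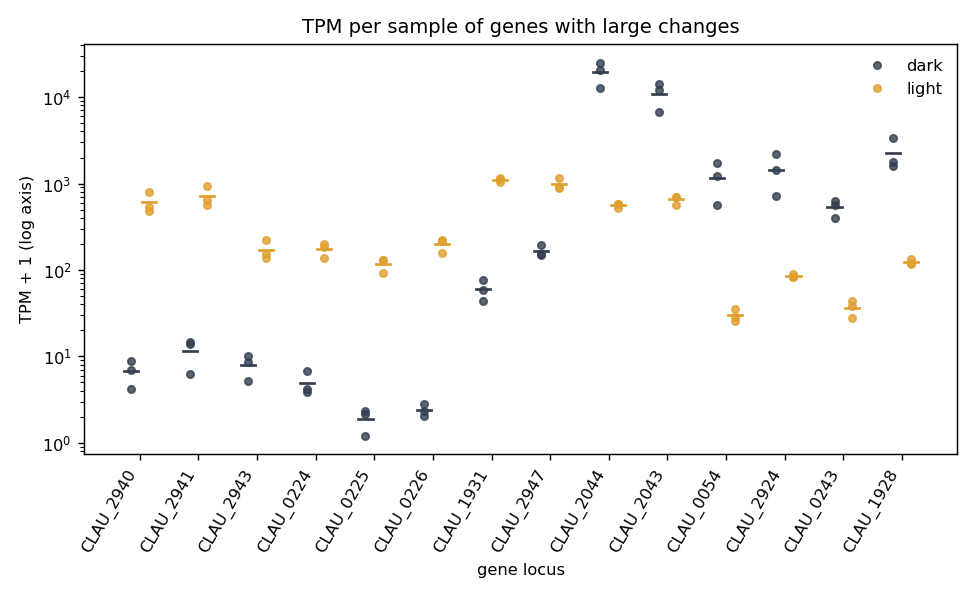
Points are the TPM of single samples plus 1, on a log axis, for 14 named genes given by locus, with dark samples in dark grey and light samples in orange, and short lines are group means. Arginine deiminase (CLAU_2940) lies at a mean of 5.69 TPM in the dark and 606 in the light, while Hsp20 (CLAU_2044) lies at 19411 and 559.8, and no gene shown has overlapping groups.

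The Wood-Ljungdahl pathway is the carbon-fixing route of this organism. Of 12 tested members, 1 rose and 6 fell in TPM (7 called when adjusted over the list alone), and after rescaling 4 rose and 2 fell. The member that rose in TPM, CLAU_0222, is annotated as formiminotransferase-cyclodeaminase, a term that the list's pattern named. It was set aside as not belonging to the pathway only after values had been seen. Without it, 3 of 11 rose and 2 fell after rescaling. The carbon monoxide dehydrogenase catalytic subunit CLAU_2924 went from 1446 ± 743 to 83.8 ± 3.57 TPM, with a log2 change of -3.95 ± 0.36 (limma adjusted p = 5.8e-06) and -2.95 after rescaling. The bifunctional methylenetetrahydrofolate dehydrogenase (CLAU_1574) fell by 2.08, and by 1.08 after rescaling, and was not called with upper-quartile rescaling (-0.64). The CO dehydrogenase/acetyl-CoA synthase delta subunits CLAU_1568 and CLAU_1569 had -1.50 and -1.48 in TPM, but were not called after rescaling (-0.50 and -0.48). The central enzymes were abundant in both groups. The acetyl-CoA synthase beta subunit (CLAU_1566) stood at 4968 ± 1059 TPM in the dark and 2573 ± 716 in the light, called lower in TPM (-0.96) but at 0.040 after rescaling, where it was not called. Without light sample 3 its TPM change was -0.80 and was not called. Both further loci annotated as carbon monoxide dehydrogenase in this region stood at 6331 ± 1633 and 7356 ± 2225 TPM (CLAU_1578, dark and light) and at 7600.5 ± 1907 and 6765 ± 2117 TPM (CLAU_1579). Neither was called in TPM (0.21 and -0.18), and both were called higher after rescaling (1.21 and 0.82). CLAU_1579 was not called with the 3 most abundant rows left out. Formate-tetrahydrofolate ligase (CLAU_1576) had a log2 change of -0.36 in TPM and 0.65 after rescaling, called in neither. It was called higher with upper-quartile rescaling (1.08) and when the replicate block was added to the median-of-ratios rescaling (0.65).

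Of 28 tested genes of acetate, ethanol, 2,3-butanediol and lactate formation, 9 rose and 9 fell in TPM (18 called when adjusted over the list alone), and after rescaling 13 rose and 4 fell. The acetaldehyde dehydrogenases CLAU_1772 and CLAU_1783 of this list lie within the main microcompartment run, CLAU_1769 to CLAU_1785. All 17 tested loci of that run were called higher after rescaling, so this list and the microcompartment list below are not fully separate results. Pyruvate ferredoxin/flavodoxin oxidoreductase (CLAU_2947), which links pyruvate and acetyl-CoA, went from 164 ± 25.3 to 990.0 ± 151 TPM, a log2 change of 2.58 ± 0.25 (limma adjusted p = 7.3e-06). A further locus with the same product, CLAU_0896, was not called higher in TPM. Acetate kinase (CLAU_3275) rose by 1.23, the bifunctional acetaldehyde-CoA/alcohol dehydrogenase CLAU_3655 by 1.30 and the aldehyde ferredoxin oxidoreductase CLAU_0099 by 1.02. After rescaling these rises were 2.22, 2.27 and 2.02. The second aldehyde ferredoxin oxidoreductase, CLAU_0089, stood at 7067 ± 2072 TPM in the dark and 2292 ± 1502 in the light, where the mean was 1438 without light sample 2. It was called lower in TPM (-1.78) but not after rescaling (-0.78). A zinc-containing alcohol dehydrogenase (CLAU_3164) and the D-lactate dehydrogenases CLAU_3388 and CLAU_0113 had log2 changes of -2.69, -2.30 and -2.73. The second acetaldehyde-CoA/alcohol dehydrogenase locus, CLAU_3656, was near the floor, at 0.807 ± 0.272 and 1.19 ± 0.196 TPM, and was called after rescaling (0.78) but not in TPM (0.29). Camera with a preset correlation called the list upward (adjusted p = 0.0187, and 0.0365 after rescaling). With an estimated correlation the adjusted p = 0.99, and 0.39 after rescaling. The call also ended without light sample 2 (adjusted p = 0.0914), without the filter on low values (0.061), with upper-quartile rescaling (0.053), without the 3 most abundant rows (0.0545) and without small RNA rows (0.0613).

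Hydrogenases, formate dehydrogenases and the energy-conserving membrane complexes held members that rose and members that fell after rescaling. Of 10 tested hydrogenase and formate dehydrogenase genes, 1 rose and 5 fell in TPM (6 called when adjusted over the list alone), and after rescaling 3 rose and 1 fell. The iron-dependent hydrogenase CLAU_1534 was listed at 0 in all dark samples and at 9.76 ± 7.31 TPM in the light, where the mean was 5.82 without light sample 1. The Fe-only hydrogenase CLAU_1535 and the maturation GTPase CLAU_2013 were called lower in TPM (-1.33 and -1.13) and not after rescaling (-0.34 and -0.22). A hydrogenase regulator (CLAU_1985) fell by 1.83, and by 0.84 after rescaling, and was not called with upper-quartile rescaling (-0.40). Of 22 tested genes in the list for the Rnf complex, ATP synthase and the Nfn transhydrogenase, 0 rose and 10 fell in TPM (8 called when adjusted over the list alone), and after rescaling 5 rose and 5 fell. Of these 22, 8 were matched by accident through the words THIF-type and ECF-type, among them 3 of the 4 with the smallest p (CLAU_0084, CLAU_2311 and CLAU_0218). Without those 8, 2 of 14 rose and 2 fell after rescaling. Rnf subunit B (CLAU_3149) fell by 1.55, and by 0.55 after rescaling. Its call ended with upper-quartile rescaling (-0.11) and when the replicate block was added to the median-of-ratios rescaling (-0.55). Rnf subunit C (CLAU_3144) had -0.55 in TPM and 0.45 after rescaling, and ATP synthase subunit beta (CLAU_2291) had -0.65 and 0.35, with no call in either. In TPM CLAU_3144 was called lower without dark sample 3 (-0.87) and CLAU_2291 without dark sample 2 (-0.89) and with the replicate block (-0.65). With upper-quartile rescaling CLAU_2291 was called higher (0.79).

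Among heat-shock chaperones and proteases more genes fell than rose. Of 31 tested members, 2 rose and 23 fell in TPM (25 called when adjusted over the list alone), and after rescaling 7 rose and 17 fell. Hsp20 (CLAU_2043) went from 10888 ± 3781 to 657 ± 82.3 TPM, next to CLAU_2044 described above. DnaJ (CLAU_2813), a co-chaperone, fell by 3.61 ± 0.29 (limma adjusted p = 2.5e-06). The list as a whole was not called by camera (adjusted p = 0.18, and 0.0817 after rescaling), and was called with the 3 most abundant rows left out (adjusted p = 0.0452). With an estimated correlation camera gave an adjusted p of 0.99, and 0.39 after rescaling. Iron uptake and Fe-S assembly genes went the same way, with 1 of 17 higher and 13 lower in TPM (14 called when adjusted over the list alone), and 3 higher and 9 lower after rescaling. FeoA (CLAU_0243), part of a ferrous iron uptake system, went from 531 ± 122 to 35.7 ± 8.02 TPM, and the transporter FeoB (CLAU_0244) fell by 2.95. The Fur family regulators CLAU_1423 and CLAU_3631 had log2 changes of -3.94 and -4.51. Camera gave an adjusted p of 0.23 for this list.

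Genes for defence against oxygen species, DNA repair and flavins held members that rose and members that fell after rescaling. Of 16 tested oxygen and thiol defence genes, 2 rose and 7 fell in TPM (8 called when adjusted over the list alone), and after rescaling 5 rose and 4 fell. Ferritin (CLAU_0025) went from 1655 ± 699.7 to 109 ± 13.0 TPM. A rubredoxin-domain protein (CLAU_0024) had a log2 change of -2.84, a rubrerythrin (CLAU_0856) of -1.83 and a redox-sensing transcriptional repressor (CLAU_1540) of -1.71. The calls of CLAU_0856 (-0.39) and CLAU_1540 (-0.36) ended with upper-quartile rescaling. Of 37 DNA repair and SOS genes, 1 rose and 13 fell in TPM (14 called when adjusted over the list alone), and after rescaling 11 rose and 5 fell. The members named by smallest p in TPM all fell, while more members rose than fell after rescaling. A locus annotated as UvrB/UvrC protein (CLAU_1928) went from 2236 ± 959.9 to 123 ± 9.55 TPM. It lies next to the gene of the repressor CtsR (CLAU_1929), a member of the heat-shock list. The UvrABC subunits are other loci (CLAU_2364, CLAU_2365 and CLAU_2370), and whether CLAU_1928 acts in DNA repair was not tested. RadA (CLAU_1925), the SOS repressor LexA (CLAU_0180) and a UvrD-like helicase (CLAU_3711) had log2 changes of -3.06, -2.45 and -2.04. The list for photoreceptor domains and flavins matched no annotated photoreceptor or photolyase. Of its 14 tested members, 1 rose and 9 fell in TPM (10 called when adjusted over the list alone), and after rescaling 3 rose and 6 fell. Lumazine synthase (CLAU_0293), of riboflavin synthesis, went from 138 ± 90.3 to 3.10 ± 0.570 TPM, and the flavodoxins CLAU_3776 and CLAU_1346 had log2 changes of -2.91 and -3.59. Pyruvate ferredoxin/flavodoxin oxidoreductase, matched through its electron carrier, was the member that rose in TPM. Camera adjusted p was 0.98, 0.89 and 0.63 for these 3 lists.

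Of 56 tested ribosomal protein genes, 0 rose and 49 fell in TPM (49 called when adjusted over the list alone), and after rescaling 5 rose and 33 fell. The median log2 change was -1.91 in TPM and -0.92 after rescaling. Ribosomal protein S14 (CLAU_1886) went from 1613 ± 116 to 189 ± 33.6 TPM, a log2 change of -3.10 ± 0.25 (limma adjusted p = 2.3e-06). S11 (CLAU_1874), a putative ribosomal protein (CLAU_3313) and L16 (CLAU_1892) had log2 changes of -3.46, -2.37 and -2.501. Their median coding length was 354 nt. The values of short genes also carry an estimated fragment length that was 202 ± 2.89 nt in the dark and 167 ± 5.77 nt in the light (SD, n = 3 each). Camera called the list downward (adjusted p = 2.2e-04, and 8.1e-04 after rescaling) but not among genes of at least 10 TPM (adjusted p = 0.126), and with an estimated correlation the adjusted p = 0.99, and 0.78 after rescaling.

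Of 98 tested flagella and chemotaxis genes, 5 rose and 69 fell in TPM (75 called when adjusted over the list alone), and after rescaling 20 rose and 50 fell. A chemotaxis sensory transducer (CLAU_0074) went from 413 ± 190.1 to 19.99 ± 2.97 TPM. A hook-length control protein (CLAU_3035), a hook-basal body protein (CLAU_3038) and the motor switch protein FliG (CLAU_3031) had log2 changes of -3.38, -2.97 and -3.36. Camera called the list downward (adjusted p = 0.0187, and 0.0126 after rescaling), but not among genes of at least 10 TPM (0.0535). With an estimated correlation the adjusted p = 0.99, and 0.39 after rescaling. Of 24 genes for bacterial microcompartments, protein shells that enclose ethanolamine or propanediol use, 12 rose and 3 fell in TPM (15 called when adjusted over the list alone), and after rescaling 16 rose and 2 fell. A shell protein (CLAU_1773) went from 29.2 ± 4.59 to 64.0 ± 4.36 TPM and EutP (CLAU_3808) from 32.5 ± 3.74 to 69.6 ± 1.55. CLAU_2724 and CLAU_3207 went the other way, with -4.25 and -2.17. Camera called the list upward (adjusted p = 2.2e-04, and 8.1e-04 after rescaling). With an estimated correlation the adjusted p = 0.99, and 0.39 after rescaling.

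Of 51 tested sporulation and germination genes, which stand for another cell state, 12 rose and 17 fell in TPM (26 called when adjusted over the list alone), and after rescaling 22 rose and 5 fell. Stage III sporulation protein AC (CLAU_3112) went from 0.530 ± 0.918 to 11.6 ± 4.74 TPM, and was listed at 0 in every dark sample but dark sample 1. A small acid-soluble spore protein (CLAU_1314), a SpoIID-domain protein (CLAU_0595) and stage II protein M (CLAU_3132) had log2 changes of -3.32, -1.99 and -1.65, the last not called with upper-quartile rescaling (-0.29). After median-of-ratios rescaling these falls were -2.44, -1.05 and -0.71. These members were named by smallest p in TPM, and their falls go against the majority of the list's calls after rescaling. Camera called the list upward in TPM (adjusted p = 0.016) but not after rescaling (0.0802), with upper-quartile rescaling (0.136), among genes of at least 10 TPM (0.848) or with an estimated correlation (adjusted p = 0.99). Of 36 prophage and mobile element genes, 7 rose and 21 fell in TPM (28 called when adjusted over the list alone), and after rescaling 12 rose and 10 fell. The integrases CLAU_0739, CLAU_0757 and CLAU_3490 had log2 changes of -3.74, -2.87 and -2.56. CLAU_2014, a metal transporter family member matched by accident, fell by 2.55. Of 8 CRISPR genes, 0 rose and 6 fell in TPM (8 called when adjusted over the list alone), and after rescaling 0 rose and 2 fell, CLAU_1360 (-1.56) and CLAU_0345 (-0.64), the second not called with upper-quartile rescaling (-0.23). CLAU_1357 and CLAU_1358 were called lower in TPM (-1.84 ± 0.43 and -1.72 ± 0.45, SE). After rescaling they had -0.92 ± 0.44 and -0.75 ± 0.50 and were not called, with an SE larger than that of CLAU_0345 (0.16). Their dark means were 27.9 and 62.7 TPM, and 17.3 and 39.4 without dark sample 2. The list for ribosomal and transfer RNA matched 1 row, the tRNA-modifying enzyme MnmA (CLAU_0384), so RNA quality was not analysed here. MnmA had -0.51 in TPM, not called, and 0.44 after rescaling, called higher. That call ended when the replicate block was added to the median-of-ratios rescaling. With a pseudocount of 10 it was called lower (-0.33).

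In amino acid synthesis, 11 of 54 tested genes rose and 29 fell in TPM (41 called when adjusted over the list alone), and after rescaling 22 rose and 13 fell. 3-dehydroquinate dehydratase (CLAU_0841) went from 258 ± 93.5 to 6.66 ± 0.584 TPM, with shikimate dehydrogenase (CLAU_0840) beside it at -3.67. The run of shikimate and chorismate genes from CLAU_0872 to CLAU_0878, chosen after its values were seen, went the other way. Of its 7 genes, 5 were called higher and 1 lower in TPM, and 6 higher and 0 lower after rescaling. Acetylglutamate kinase (CLAU_0230), of arginine synthesis, fell by 2.79. Ornithine carbamoyltransferase, described above, is also in this list. Of 19 purine and pyrimidine genes, 3 rose and 9 fell in TPM (12 called when adjusted over the list alone), and after rescaling 8 rose and 2 fell. Orotate phosphoribosyltransferase (CLAU_1436) and orotidine phosphate decarboxylase (CLAU_1439), of pyrimidine synthesis, rose by 1.63 and 1.55. The purine genes CLAU_2869 and CLAU_2868 had log2 changes of -2.62 and -2.49. Of 30 nitrogen genes, 3 rose and 11 fell in TPM (13 called when adjusted over the list alone), and after rescaling 15 rose and 7 fell. An ammonium transporter (CLAU_2042), a P-II regulator (CLAU_2040) and the nitrogenase-like proteins CLAU_0360 and CLAU_0359 had log2 changes of -2.92, -2.67, -2.90 and -2.10. After rescaling these were -2.09, -1.70, -1.90 and -1.11. They were named by smallest p in TPM and go against the majority of the list's calls after rescaling. Of 31 sulfur, cysteine and methionine genes, 3 rose and 16 fell in TPM (19 called when adjusted over the list alone), and after rescaling 10 rose and 10 fell. A methionine synthase activation protein (CLAU_0391) went from 687 ± 92.5 to 28.3 ± 9.93 TPM, and cysteine synthase (CLAU_1729), methionine synthase (CLAU_0152) and a sulfite reductase (CLAU_1587) had log2 changes of -2.68, -3.39 and -2.17. Camera called none of these 4 lists (adjusted p 0.43, 0.32, 0.37 and 0.98).

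Among cofactor genes, 5 of 56 cobalamin and tetrapyrrole genes rose and 35 fell in TPM (40 called when adjusted over the list alone), and after rescaling 14 rose and 15 fell. A cobalamin synthesis protein (CLAU_0142), a uroporphyrinogen decarboxylase family protein (CLAU_0136), a cobalamin-binding protein (CLAU_2765) and CbiM (CLAU_1181) had log2 changes of -3.20, -3.002, -2.19 and -3.12. The dark mean of CLAU_1181 was 527 TPM, and 302 without dark sample 2. Of 21 loci in the cobalamin synthesis run CLAU_1073 to CLAU_1093, chosen after its values were seen, 2 were called higher and 12 lower in TPM. After rescaling 6 were higher and 1 lower, so most of the list's 15 lower calls lay outside this run. Of 29 molybdenum and tungsten genes, 1 rose and 20 fell in TPM (23 called when adjusted over the list alone), and after rescaling 6 rose and 13 fell. The list includes enzymes that carry the cofactor. CLAU_2330, next to CLAU_2331, went from 497 ± 207 to 17.1 ± 4.15 TPM, and the cofactor genes CLAU_0552 and CLAU_0550 had log2 changes of -3.59 and -3.03. Of 28 vitamin genes, 1 rose and 20 fell in TPM (21 called when adjusted over the list alone), and after rescaling 5 rose and 8 fell. Quinolinate phosphoribosyl transferase (CLAU_2329), a thiamine S protein (CLAU_0083), lipoyl synthase (CLAU_1182) and a dihydropteroate synthase family protein (CLAU_1567) had log2 changes of -4.84, -3.94, -2.30 and -2.54. CLAU_1567, at -1.54 after rescaling, lies between the acetyl-CoA synthase subunits CLAU_1566 and CLAU_1568. The Wood-Ljungdahl list does not hold it, and whether it acts in vitamin synthesis was not tested. Camera adjusted p was 0.68, 0.19 and 0.37 for these 3 lists.

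Of 26 sugar uptake and glycolysis genes, 2 rose and 16 fell in TPM (18 called when adjusted over the list alone), and after rescaling 7 rose and 7 fell. Phosphoglycerate dehydrogenases (CLAU_2158 and CLAU_1027), the phosphocarrier HPr (CLAU_3334) and phosphoenolpyruvate carboxykinase (CLAU_2645) had log2 changes of -2.60, -1.96, -2.27 and -2.07. After rescaling these were -1.63, -0.98, -1.27 and -1.08. The dehydrogenases and the carboxykinase were matched through the words phosphoglycerate and phosphoenolpyruvate. Their product names do not place them in sugar uptake or glycolysis. Of 36 peptidoglycan and cell division genes, 1 rose and 22 fell in TPM (23 called when adjusted over the list alone), and after rescaling 10 rose and 12 fell. A peptidoglycan glycosyltransferase (CLAU_1684), MinD (CLAU_2741), ZapA (CLAU_1300) and Maf (CLAU_2734) had log2 changes of -3.18, -2.60, -2.86 and -2.37. Camera adjusted p was 0.89 and 0.49. The remaining lists, for the Wood-Ljungdahl pathway, hydrogenases, the membrane complexes, prophage and CRISPR, had adjusted p of 0.98, 0.89, 0.72, 0.89 and 0.39. In all, camera called 5 of 24 lists in TPM and 4 after rescaling, and 0 with an estimated correlation, where 0 had an unadjusted p under 0.05 in TPM and 2 after rescaling. Fry, which asks whether a list's genes move one way without comparing them with other genes, called 19, and 12 after rescaling. Relative to the median of all tested genes in TPM, the median of the list and the direction of camera differed in sign for the Wood-Ljungdahl pathway (0.13), the membrane complexes (0.14) and oxygen defence (0.32), where camera pointed down. They differed also for amino acid synthesis (-0.03) and prophage (-0.09), where it pointed up. The medians for the Wood-Ljungdahl pathway and amino acid synthesis changed sign when single samples were left out, dark sample 1 for both and also dark sample 3 or light sample 1 for the second. For sulfur genes camera pointed up, while the median and mean after rescaling were -0.04 and -0.12.

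**Figure D3:**
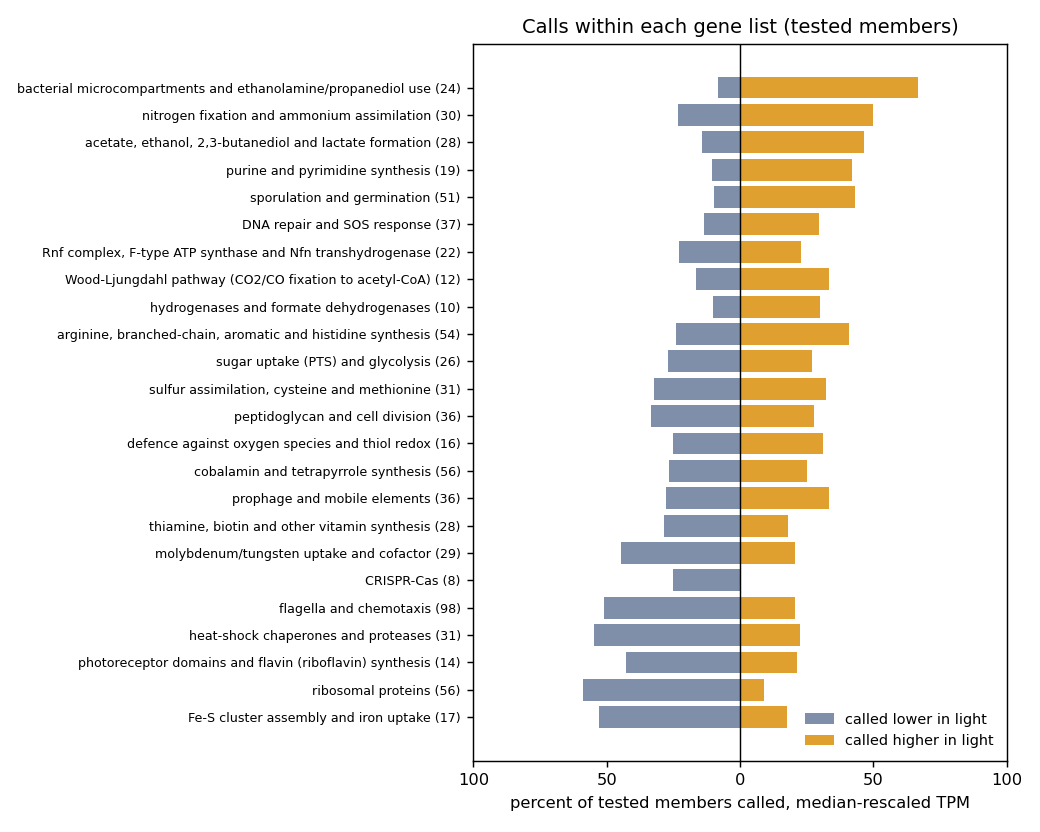
For each of 24 gene lists, with the number of tested members in brackets, bars give the percentage of members called lower (left) and higher (right) in light by limma on TPM rescaled by the median of ratios. Lists are ordered by median log2 change, from microcompartments, with 16 of 24 members higher, to iron uptake and Fe-S assembly, with 9 of 17 lower.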

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

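Rescaling, leaving out abundant or small RNA rows, the filter at 10 TPM, moderation, lists without accidental members, and rescaling together with the block or fry were chosen after seeing the data; the other alternatives were planned. The count of called genes stayed within 1.5 times of 2274 in all settings run. Its split did not, and the cause is in part the construction of each scaling. Genes called higher (398) and lower (1876) became 1073 and 1030 with median-of-ratios rescaling, 1395 and 731 with upper-quartile rescaling, and 1057 and 1122 without the 3 most abundant rows. Without small RNA rows 727 were higher, and at a mean of at least 10 TPM, which tests fewer rows, 187. Of the 2-fold calls (1800, with 241 higher and 1559 lower), a pseudocount of 10, which shrinks low values, left 1040, with 87 and 953. Median-of-ratios rescaling gave 685 and 748, upper-quartile rescaling 1008 and 514, and leaving out the 3 most abundant rows 797 and 907. Without small RNA rows 492 were 2-fold higher, and at 10 TPM 137.

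Of 5 called lists, 0 were called with an estimated correlation, 3 after upper-quartile rescaling and 2 at 10 TPM; the cause was not tested. Fry, which tests each list against no change, called 19, and 12 after median-of-ratios rescaling. Counted as reversed is a change of sign in a gene called before or after it. With upper-quartile rescaling these named genes were CLAU_1535 (0.10), CLAU_2013 (0.17), CLAU_0384 (0.85), CLAU_1566 (0.48), CLAU_1576 (1.08), CLAU_1579 (1.26) and CLAU_2291 (0.79), on the log2 scale; CLAU_0384, CLAU_1576, CLAU_1579 and CLAU_2291 were then called higher. A further 12 kept their sign and lost their call: CLAU_1574, CLAU_1568, CLAU_1569, CLAU_1985, CLAU_3149, CLAU_1540, CLAU_0856, CLAU_3132, CLAU_0345, CLAU_1357, CLAU_1358 and CLAU_0089. With median-of-ratios rescaling CLAU_0384 (0.44) and CLAU_1579 (0.82) were reversed and called higher, and CLAU_1566 (0.040) lost its call at a value near 0. CLAU_1576, CLAU_3144 and CLAU_2291 changed sign without a call in either. With the 3 most abundant rows left out, neither CLAU_0384 nor CLAU_1579 was called. The median of all tested genes moved from -0.82 in TPM to 0.34 with upper-quartile rescaling.

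Deviations of same-numbered samples from their group means had weak positive correlations (0.12, 0.03 and 0.048), and dark sample 3 correlated best with light sample 2 (0.0778). With 3 samples per group these values cannot decide whether the numbers pair the samples. With the replicate block 2349 genes were called, 427 higher and 1922 lower, CLAU_2291 (-0.65) now among the lower. With median-of-ratios rescaling and the replicate block 1040 were higher and 1019 lower, 699 and 757 by 2-fold. CLAU_1576 (0.65) and CLAU_1579 (0.82) were called higher, and CLAU_1566 (0.040) was not called. CLAU_3149 lost its lower call and CLAU_0384 its higher call. Leaving out each sample in turn gave 2023 to 2216 called genes, and those shared with the 2274 had the same sign. Alternatives that need counts, and one without rRNA and tRNA genes, which matched no RNA gene here, were not run.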

Other observations

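The tests of scaling and of gene length were chosen after their results were seen, and the rescaling used in 1 of the tests on splits of the samples was added after seeing the data; the other tests on splits were planned.

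Runs of neighbouring loci were chosen after their values were seen, and some moved together. All 9 tested loci from CLAU_2328 to CLAU_2336 were called lower, with a median log2 change of -5.36 in TPM and -4.41 after rescaling. The nitrate reductase subunits CLAU_2922 and CLAU_2923, next to the carbon monoxide dehydrogenase subunit CLAU_2924, had -3.36 and -3.38 after rescaling. All 17 tested loci of the main microcompartment run, CLAU_1769 to CLAU_1785, were called higher after rescaling, 16 of them also in TPM. In the second run, CLAU_3195 to CLAU_3207, 4 of 12 were called higher and 1 lower after rescaling, and 1 higher and 1 lower in TPM. All 7 tested tryptophan synthesis loci, CLAU_3611 to CLAU_3617, were called higher after rescaling and 4 in TPM. Both glycine cleavage loci CLAU_0455 and CLAU_0456 and all 4 riboflavin loci from CLAU_0293 to CLAU_0296 were called lower in TPM and after rescaling. In other runs the balance of higher and lower calls depended on the scale. Of 21 cobalamin synthesis loci from CLAU_1073 to CLAU_1093, 2 were called higher and 12 lower in TPM, and 6 higher and 1 lower after rescaling. Of 10 histidine synthesis loci from CLAU_3174 to CLAU_3183, 0 were called higher and 8 lower in TPM, and 1 higher and 1 lower after rescaling. Of 7 nitrogenase loci from CLAU_2502 to CLAU_2508, 0 were called higher and 1 lower in TPM, and 3 higher and 0 lower after rescaling. Of 14 loci from CLAU_1566 to CLAU_1579, which hold the Wood-Ljungdahl genes, 0 were called higher and 9 lower in TPM, and 3 higher and 2 lower after rescaling. The alcohol dehydrogenase CLAU_1794, also chosen after its values were seen, went from 2023 ± 631 TPM (SD, n = 3) in the dark to 7770.1 ± 659.9 (n = 3) in the light.

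Of 72 tested small RNA rows, 22 were called higher and 42 lower in TPM, and 24 and 38 after rescaling. CLAU_2841, the most abundant locus in the light, lies beside the gene of the RNase P RNA in the RefSeq table. Whether its reads come from that RNA was not tested.

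The median gene was lower in TPM under light, with a log2 change of -0.82. The share of TPM outside the 3 most abundant rows changed by -0.85 on the log2 scale. By arithmetic this moves every other row by that much in log2 TPM, and low rows by less in log2(TPM + 1). The median of -0.020 with the 3 rows left out, over 3844 tested rows against 3530, largely restates this and is no separate test. Among rows with a mean of at least 10 TPM in one group the median change was -1.45, a larger shift than the share alone gives. That filter can itself favour falls, because a row may pass through its dark values alone. The median TPM of tested rows was 12.2 in the dark and 5.81 in the light. How much of the excess comes from the filter was not tested. TPM cannot show whether those rows rose or the other RNA per cell fell, so both stay open.

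Ribosomal protein genes, which are short, were lower under light, and shorter fragments in the light libraries could lower the TPM of short genes. Their median log2 fold in the authors' deposited table was -0.86, below the central 95% (-0.69 to 0.34) of 10000 random lists matched on length. In TPM it was -1.91 against -1.52 to -0.55, so the list fell further than most random lists of such lengths. The random lists were matched gene by gene, while ribosomal protein genes had an estimated correlation of 0.58. The random range is too narrow for genes that move together, and the comparison does not decide whether length is the whole cause. The median of -0.92 after median-of-ratios rescaling largely restates the list's distance of -1.09 from the median tested gene in TPM. It is no separate test, because rescaling multiplies all rows of a sample by 1 factor. The list lay below the median gene, but low rows move less than abundant ones in log2(TPM + 1). Among genes of at least 10 TPM the distance was -0.50. These values do not decide how much of the fall comes from scaling. The list's call was lost with an estimated correlation and among genes of at least 10 TPM. A difference in growth between the cultures stays open and was not tested.

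With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split called 2274 rows and 1800 by 2-fold, and the highest of the others 0 in each; 1 split of the 10, the real one, gave as many. After rescaling these were 2103 and 1, again with 1 split as large. For gene lists the real split called 5 and the highest other also 5, and 3 of the 10 splits gave as many.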
